A study of Mus musculus with 10 samples.

How the data were processed

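Single-nucleus RNA was measured in the brains of male mice whose striatum had received 10000 HGG17 glioma cells, harvested at day 28, or that had a sham injection, for which the labels give no day. Of the 10 samples of the series, 9 had a count matrix and 10 matrices were read. They were 8 libraries of nuclei (6 allografts, 3 per host genotype, and 2 shams, 1 per genotype) and 1 in vitro sample of HGG17 cells in 2 matrices, labelled as polyA RNA. The source label reads brain tumour for the shams too. The deposited values were UMI counts per gene and barcode, made by the authors with Cell Ranger 8.0.0 from Chromium 3' kit 3.1 libraries against GRCm39, per the submitters' processing notes, which also name Seurat 5. No coordinates were used. The labels give replicate numbers and nothing on separate animals, so p-values measure the spread between these samples.

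Counts were read with Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6 and scipy 1.17.1, with seed 1. Barcodes with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs were kept. This left 20587, 13600 and 14171 nuclei in Nf1+/- allografts 1 to 3 (median UMIs 4262, 1776 and 2987), 29204, 16035 and 13741 in wild-type allografts 1 to 3 (3131, 1691 and 2736), 1375 of 25058 barcodes in the Nf1+/- sham (10893) and 5086 of 7234 in the wild-type sham (6974). The median mitochondrial share of the Nf1+/- sham before the filter was 30.8%. Doublets were scored with Scrublet, and the highest-scoring 0.8% per 1000 nuclei of each library were removed, because its automatic threshold failed. This took out 3390, 1479 and 1606 nuclei in the Nf1+/- allografts, 6822, 2056 and 1510 in the wild-type allografts, and 15 and 206 in the shams.

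Nuclei were scaled to 10000 counts, and 2500 variable genes, 40 components and 20 neighbours were used for Leiden clustering (igraph 0.11.9) at resolution 1. Clusters were named by the highest of 16 marker scores (glioma, microglia, macrophage, dendritic, T/NK, B, neutrophil, oligodendrocyte, OPC, astrocyte, neuron, endothelial, mural, fibroblast, ependymal and choroid plexus). A name needed a log2 score of at least 0.4 with a pseudocount of 10 CPM, a gap of 0.2 to the next class and 3 markers detected. A cluster also stayed unnamed if another class had more markers among its 10 top genes than the best class. The same held for a cluster far shallower than its libraries with none of its own markers there. Cluster 36, with oligodendrocyte as best class (2.25, next glioma 1.00), stayed unnamed by the rule on top genes. Clusters with over 50% doublets stayed unnamed. Clusters with glioma markers, a median of at least 20% ribosomal protein UMIs and under 2000 UMIs were called RP-rich droplets and kept out of the glioma-like class. No cluster was named dendritic, B, neutrophil, endothelial, mural, fibroblast or ependymal.

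Counts were summed per library and class where at least 10 nuclei were present, and host genotypes were compared in glioma-like, microglia-like and macrophage-like nuclei and in each further class with at least 50 nuclei in each of the 6 allografts. The macrophage-like sum of Nf1+/- allograft 1 held 33 nuclei. Tests were made in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, TMM, low counts filtered) at a Benjamini-Hochberg adjusted p of 0.05, and repeated with DESeq2 1.42.0. Allografts and shams were compared with genotype in the fit. Cd74-positive and Cd74-negative glioma-like nuclei were summed within each library (at least 5 nuclei per sum) and compared with the library as a block. Shares were compared by exact permutation tests over 10 splits. Cd74 shares were counted after each nucleus was thinned to 1000 UMIs, with exact 95% binomial intervals.

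Gene lists were tested with limma 3.58.1: camera with a preset correlation of 0.01, camera with an estimated correlation, and fry. The 20 lists were MHC class II, MHC class I, interferon gamma response, type I interferon response, co-stimulation and checkpoint ligands, RAS/MAPK output, proliferation, mesenchymal glioma, hypoxia and angiogenesis, extracellular matrix, homeostatic microglia, disease-associated microglia, chemokines and cytokines, tumour-associated macrophage suppression, reactive astrocyte, oligodendrocyte stress, T cell state, immediate early and dissociation stress, mitochondrial RNA and sex-linked genes. The marker lists were tested in the same way.

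Genes were named by a fixed rule: Nf1, Cd74, H2-Aa, H2-Ab1, H2-Eb1 and Ciita where measured; list members past the threshold, up to 4 per list; and the 6 largest rises and falls with a mean of at least 10 CPM and no overlap of groups, leaving out ribosomal, mitochondrial and unnamed genes. Where under 5 genes passed, all of them and the 3 smallest p-values were named. Some genes that this rule names are not reported here. A gene at 0 in a whole group got a lower bound of its fold from a floor of 3 counts over that group, and a gene with 1 to 3 counts a ratio of summed counts with a counting interval.

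Groups, comparisons, lists, naming rule and most alternatives were set before the data were examined. The mitochondrial limit of 10%, the doublet rule, the naming thresholds, the class of RP-rich droplets and the alternatives of a 5% mitochondrial limit, a naming gap of 0.4, RP-rich droplets kept, free RNA subtracted, the replicate number as a block in the sham comparisons and the expected Cd74 share over all thinning draws were chosen after the files were seen. Free RNA was estimated from the RP-rich droplets of a library with at least 100 of them, scaled by up to 44 glioma-only genes (at least 100 CPM in vitro and at most 2 CPM in shams). Nf1+/- allograft 1, with 59 such droplets, had no estimate, so its counts stayed as they were. Other alternatives were DESeq2, its size factors, no filter on low counts, a minimum of 1000 UMIs, doublets kept, Leiden resolution 2, thinning to 500 UMIs or none, and each library left out.

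Same-numbered replicates of the 2 genotypes were checked for pairing by the correlation of their deviations from the group means. In neuron-like nuclei the correlations were 0.485, 0.266 and 0.418 for replicates 1, 2 and 3, all above 0.1, and the pairing comes from these values and not from the labels; the fit with this block called 0 genes, as did the fit without it. On simulated data with 100 genes changed, the genotype test recovered 5% at 2-fold and 90% at 4-fold in glioma-like nuclei, and 5% and 72% in microglia-like nuclei. The sham comparison in microglia-like nuclei recovered 0% and 16%, and the Cd74 comparison 100% and 100%. Changed genes were drawn only from the more highly expressed ones, so recovery of genes at a few CPM was not measured. Each gene was simulated on its own, without spread shared across genes, so recovery in the real libraries may differ. In vitro cells and in vivo nuclei were described without a test.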

Results

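Single-nucleus RNA counts were measured in the brains of male mice, in allografts harvested 28 days after 10000 HGG17 high-grade glioma cells had been placed in the striatum and in sham-injected brain. Hosts were heterozygous for Nf1, the gene of the RAS inhibitor neurofibromin, or wild type, with 3 allograft libraries per genotype and 1 sham-injected library per genotype. Total UMI counts lay between 93362983 and 151309226 in the Nf1+/- allografts and between 108007774 and 129108710 in the wild-type allografts. The Nf1+/- sham held 59504969 UMIs and the wild-type sham 53316130. After filtering, 48358 nuclei remained in the Nf1+/- allografts, 58980 in the wild-type allografts, 1375 in the Nf1+/- sham and 5086 in the wild-type sham. HGG17 cells grown in vitro were 1 further sample, with 2119 cells in 2 matrices and no replicate.

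Nf1 transcripts were counted in every library. In neuron-like nuclei, which carry the host genotype, Nf1 stood at 287, 187 and 185 CPM in Nf1+/- allografts 1 to 3 and at 207, 223 and 215 CPM in wild-type allografts 1 to 3. The Nf1+/- sham had 302 CPM and the wild-type sham 271 CPM. Reads from the 3' end of a heterozygous allele do not check the genotype labels, because the altered allele can still give such reads.

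The first question was which cells each genotype's tumours held. Glioma-like nuclei, named by a marker list that holds Hmga2, a chromatin protein of embryonic growth, and the growth factor receptor Met, made up 19.6% ± 7.02 (SD, n = 3) of nuclei in Nf1+/- hosts and 32.03% ± 20.8 (n = 3) in wild-type hosts. Microglia-like nuclei, the resident brain macrophages, made up 4.504% ± 2.70 (n = 3) and 2.81% ± 0.572 (n = 3). Macrophage-like nuclei made up 1.74% ± 1.56 (n = 3) and 3.79% ± 3.03 (n = 3), and T/NK-like nuclei 0.712% ± 0.536 (n = 3) and 1.07% ± 0.878 (n = 3). None of these differences passed. Exact permutation tests gave p = 0.4 for glioma-like, 0.4 for microglia-like, 0.3 for macrophage-like and 0.7 for T/NK-like nuclei, with 0.1 the smallest p that 3 against 3 libraries allow. Wild-type allograft 1 held 12267 of the glioma-like nuclei, and the difference in their share went from -12.5 to -1.08 percentage points without it and to -21.4 without wild-type allograft 2. The microglia-like difference of 1.69 points went to 0.162 without Nf1+/- allograft 1, to 2.72 without Nf1+/- allograft 2 and turned to -0.350 as a share of host nuclei (10.2% against 10.6%, exact permutation p = 1). That in T/NK-like nuclei, -0.356 points, went to 0.124 without wild-type allograft 3, to -0.738 without wild-type allograft 1, and to -0.177, -0.664 and -0.227 without Nf1+/- allografts 1, 2 and 3. The macrophage-like difference of -2.05 points went to -0.889 without wild-type allograft 3, to -1.27 without Nf1+/- allograft 1 and to -3.77 without wild-type allograft 1. As shares of host nuclei the differences were -4.95 points for macrophage-like and -0.680 for T/NK-like nuclei.

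Neuron-like nuclei made up 26.4% ± 14.4 (n = 3) of Nf1+/- and 17.7% ± 2.39 (n = 3) of wild-type allograft nuclei. Oligodendrocyte-like nuclei made up 7.24% ± 12.01 (n = 3) and 0.314% ± 0.259 (n = 3), and Nf1+/- allograft 1 alone held 3629 of them. The other allografts held 21 to 75 each, a count that depends on naming. Cluster 36, left unnamed with oligodendrocyte as its best class and glioma next, held 7, 186 and 169 nuclei in Nf1+/- allografts 1 to 3. In wild-type allografts 1 to 3 it held 928, 214 and 289. At Leiden resolution 2 a cluster of 1456 nuclei, 46.0% from wild-type allograft 1, was named oligodendrocyte. In sums of all nuclei, log2 CPM of Nf1+/- allograft 1 correlated with the other 5 allografts at 0.839 to 0.898 (Pearson), and these 5 with each other at 0.949 to 0.987. In the shams, neuron-like nuclei made up 87.6% (Nf1+/-) and 64.2% (wild type), and 0 and 2 nuclei were glioma-like. A large part of the allograft barcodes carried glioma markers in clusters with a median ribosomal protein share of at least 20% and under 2000 UMIs. These RP-rich droplets, 29.4% ± 26.4 (n = 3) of Nf1+/- and 35.4% ± 16.7 (n = 3) of wild-type nuclei, were kept apart from the glioma-like class. The shares also depend on how much tumour each dissected piece held, which the labels do not give.

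**Figure D1:**
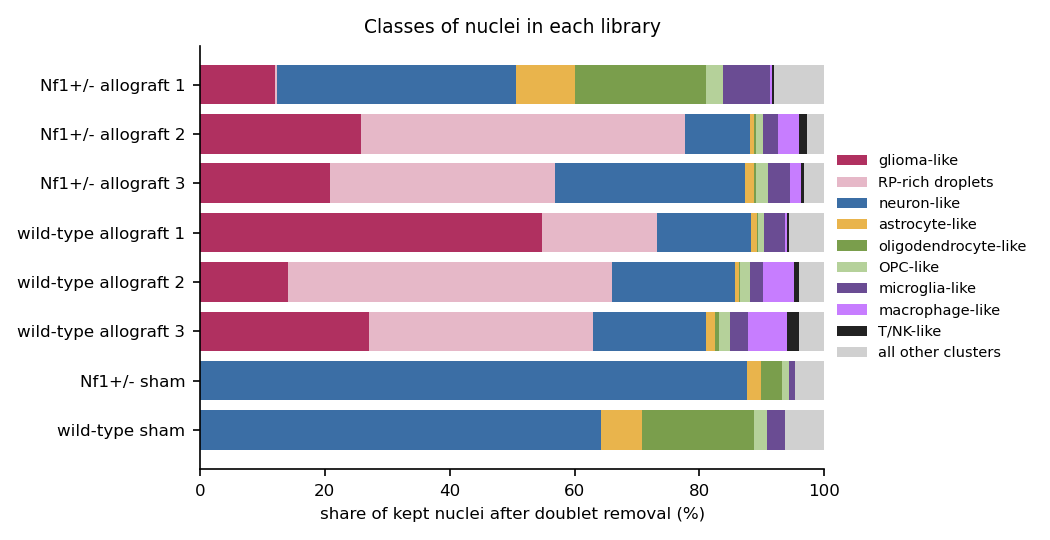
Percent of kept nuclei after doublet removal (x axis) in each class, stacked, for the 8 libraries of nuclei (y axis). Nf1+/- allograft 1 held 3629 oligodendrocyte-like nuclei, and wild-type allograft 1 held 12267 glioma-like nuclei.

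The title of the series concerns glioma cells positive for CD74, the invariant chain that guides MHC class II molecules to their peptides. After each nucleus was thinned to 1000 UMIs, a Cd74 UMI was found in 1.43% ± 1.16 (SD, n = 3) of glioma-like nuclei in Nf1+/- hosts and in 5.72% ± 4.54 (n = 3) in wild-type hosts. Neuron-like and oligodendrocyte-like nuclei were taken as the background. Neuron-like nuclei had 1.61% ± 1.22 (n = 3) and 5.33% ± 4.23 (n = 3). Oligodendrocyte-like nuclei, few in most allografts, had 1.39% ± 1.48 (n = 3) and 9.90% ± 9.55 (n = 3). Library by library the values ran together: glioma-like shares were 0.194%, 2.49% and 1.60% in Nf1+/- allografts 1 to 3 and 0.505%, 8.78% and 7.87% in wild-type allografts 1 to 3, against 0.334%, 2.77%, 1.73%, 0.534%, 6.92% and 8.54% in neuron-like nuclei of the same libraries. Macrophage-like nuclei stood at 61.2% ± 3.64 (n = 3) and 69.1% ± 6.49 (n = 3).

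These values come from 1 random draw, and others differ from it by chance: in Nf1+/- allograft 1 the draw gave 0.194% against an expected 0.300% over all draws. The expected glioma-like shares were 0.300%, 2.44% and 1.79% in Nf1+/- allografts 1 to 3 and 0.532%, 9.06% and 7.43% in wild-type allografts 1 to 3. Those of neuron-like nuclei were 0.314%, 2.68%, 1.68%, 0.513%, 6.63% and 8.12%, so the glioma-like share was the higher one in 3 of 6 libraries, by most in wild-type allograft 2. Whether it exceeded the background there was not tested. The genotype difference of -4.29 points gave p = 0.3 in the exact permutation test (n = 3 and 3, smallest possible p 0.1). With expected shares it was -4.17 points (p = 0.3 in the same exact test, n = 3 and 3). It moved to -6.90 points without wild-type allograft 1, to -2.76 without wild-type allograft 2, to -2.37 when thinned to 500 UMIs, to -0.343 for at least 2 Cd74 UMIs and to -9.76 with RP-rich droplets kept (3.02% against 12.8%). Median depths of the nuclei counted were 1332 to 5265 UMIs in the glioma-like and 4134 to 10920 in the neuron-like class. Without thinning, the glioma-like shares were 6.13% ± 5.48 (n = 3) and 23.9% ± 19.2 (n = 3). In Nf1+/- allograft 1, 1029 of 2058 glioma-like nuclei were too shallow to thin and were left out. In the shams, 0 of 1190 thinned neuron-like nuclei (Nf1+/-), which allows up to 0.310% by the exact interval, and 0.159% (wild type) had a Cd74 UMI, with expected shares of 0.128% and 0.112%.

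**Figure D2:**
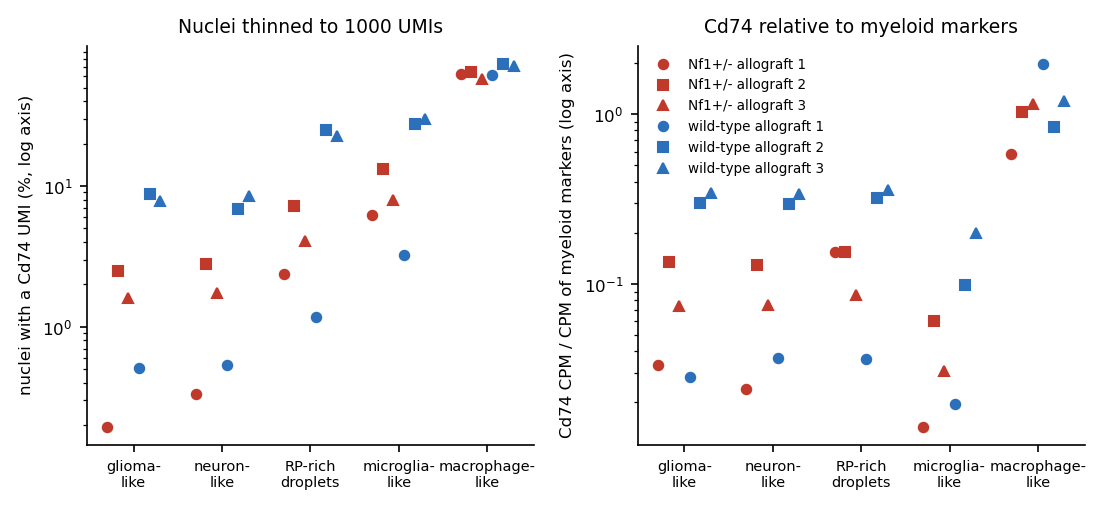
Percent of nuclei thinned to 1000 UMIs with a Cd74 UMI (left, y axis, log scale) and Cd74 CPM over the CPM of myeloid markers (right, y axis, log scale) by class (x axis) in the 6 allograft libraries. Macrophage-like nuclei lie between 57.1% and 74.01% on the left.

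The next comparison asked which genes go with Cd74 within glioma-like nuclei of the same library. Ptprc, the leukocyte surface phosphatase CD45, was higher in Cd74-positive nuclei by 0.91 on the log2 scale (SE 0.18; 7.64 ± 5.91 against 3.12 ± 0.452 CPM, n = 6 libraries; higher in 5 of 6). Its highest value, 19.4 CPM, came from the positive sum of Nf1+/- allograft 1, with 9 nuclei and 38982 UMIs. In that sum 10 Cd74 UMIs gave 194 CPM. The positive sums of the other libraries had 3.34 to 7.08 CPM of Ptprc. Mbp, a myelin protein, rose by 0.27 and H2ac8, a histone, by 0.25. St18, a transcription factor of oligodendrocytes, passed with a fitted log2 of 0.52 and was higher in 4 of 6 libraries, while its mean was lower in positive sums (12.9 ± 5.68 against 14.5 ± 14.3 CPM). Ttr, the thyroxine carrier of the choroid plexus, fell by 0.85 (SE 0.08) and the unnamed transcript D030024E09Rik fell by 0.87. H2-Ab1, a class II chain, was higher in 6 of 6 libraries but did not pass (log2 0.38, edgeR adjusted p = 0.942). In the positive sum of Nf1+/- allograft 1 it stood at 19.4 CPM, the same value as Ptprc. H2-Aa (0.25), H2-Eb1 (0.18) and Nf1 (0.00) did not pass either. Ciita, the class II transcription regulator, did not pass and had no clear direction, with a fitted log2 of 0.24 but higher values in only 2 of 6 libraries and means of 1.88 and 2.40 CPM in positive and negative sums.

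These were the 6 genes past an adjusted p of 0.05 among 14642 in edgeR's quasi-likelihood test with the library as a block, leaving out Cd74 itself. The count went to 12 without wild-type allograft 1 and to 13 without wild-type allograft 2, and the sum of Cd74-positive nuclei in Nf1+/- allograft 1 held only 9 nuclei. With nuclei thinned to 1000 UMIs, 3 genes passed and none of the 6: H2-Ab1 (1.44) and Lyz2 (1.29), the lysozyme of macrophages, were higher and Hsp90ab1, a chaperone, was lower (log2 -0.53). With nuclei that held any UMI of a microglia or macrophage marker left out, 3 others passed, H1f5, Pafah1b3 and Selenow, all lower. These genes of alternative fits were named after their values were seen.

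Among gene lists, oligodendrocyte markers were higher in Cd74-positive nuclei (9 of 9 positive, 2 rose, 5 passed when adjusted over the list alone; camera adjusted p = 1.4e-11, 0.0207 with an estimated correlation, fry 0.0137). Sex-linked genes, of which Y genes mark male host nuclei, had a camera adjusted p of 3.5e-04, which was lost with an estimated correlation (0.149), and a fry adjusted p of 0.00850. Macrophage markers (6 of 6 positive) had a camera adjusted p of 2.1e-04 and 0.0723 with an estimated correlation. The other MHC class II genes (5 of 6 positive, 0 rose, 2 passed when adjusted over the list alone) had 0.00518 and 0.678. OPC markers had 0.0235 (lower) and 0.290, co-stimulation and checkpoint ligands 0.0177 and 0.678, and disease-associated microglia genes 0.0446 and 0.724. A class split on 1 UMI of 1 gene depends on depth and background.

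The comparison of host genotypes asked whether the Nf1+/- brain changes the tumour or the cells around it. In glioma-like nuclei, Cd74 stood at 10.4 ± 6.71 CPM (SD, n = 3) in Nf1+/- and 36.2 ± 28.6 CPM (n = 3) in wild-type hosts, a log2 difference of -1.72 (SE 0.93) that did not pass. H2-Aa (-1.46), H2-Ab1 (-1.64), H2-Eb1 (-1.33), Ciita (-0.59) and Nf1 (-0.11) did not pass either. The smallest p-values belonged to the unnamed transcript Gm49313 (log2 2.10), Igfbpl1, a growth factor binding protein of developing neurons (-1.09; 14.0 ± 3.22 against 29.9 ± 3.48 CPM), and Grik2, a kainate receptor (1.36; 70.8 ± 27.1 against 27.4 ± 1.502 CPM), none of which passed. Most glioma-like nuclei of Nf1+/- allograft 1 were in cluster 3 and most of wild-type allograft 1 in cluster 12, so values within the class also compare different clusters.

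edgeR called 0 of 17608 genes in glioma-like nuclei at an adjusted p of 0.05, with 175 at an unadjusted p under 0.05. Those were 381 and 95 without Nf1+/- allografts 1 and 3 and 97 and 1394 without wild-type allografts 2 and 3. DESeq2 called 1, Gm49313. MHC class I genes were on balance lower (1 of 15 positive, median log2 -0.87, 0 passed when adjusted over the list alone; camera adjusted p = 0.0113, 0.894 with an estimated correlation). Astrocyte markers were higher in the same test and neuron markers lower (camera 0.0123 and 0.0278; 0.366 and 0.740 with an estimated correlation). Simulated counts, drawn for each gene alone with its spread in these libraries, gave calls for 90% of genes changed 4-fold and 5% of genes changed 2-fold. Spread that many genes share, as along the first component below, was not simulated, so recovery in the real libraries may differ. Only the more highly expressed genes were changed there, so recovery at low counts was not measured.

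**Figure D3:**
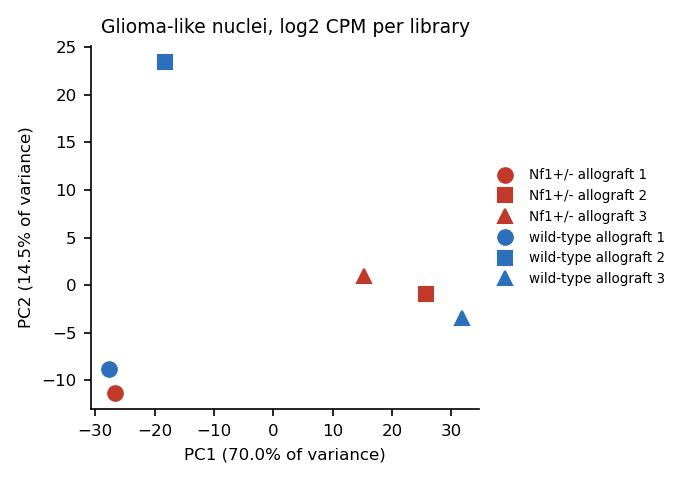
First and second principal component of log2 CPM in glioma-like nuclei (axes with 70.0% and 14.5% of the variance) for the 6 allograft libraries, coloured by host genotype. Nf1+/- allograft 1 and wild-type allografts 1 and 2 lie below 0 on the first component, and the other 3 libraries lie above it.

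In macrophage-like nuclei, S100a9, a calcium-binding protein of neutrophils, stood at 657 ± 583 CPM (n = 3) in Nf1+/- and 38.1 ± 12.4 CPM (n = 3) in wild-type hosts, with every Nf1+/- library above every wild-type one (log2 3.99, SE 0.69, edgeR adjusted p = 0.902). The highest value, 1313 CPM against 197 and 461 CPM in Nf1+/- allografts 2 and 3, came from Nf1+/- allograft 1, whose sum held 33 nuclei, and without it the log2 of S100a9 was 2.99. DESeq2 and the fit without a filter on low counts called it (adjusted p 2.2e-08 and 1.4e-09), and over its alternatives the adjusted p ran from 1.4e-09 to 1. Neutrophil markers as a list were higher (4 of 4 positive, 3 passed when adjusted over the list alone; camera adjusted p = 4.7e-07, 0.1001 with an estimated correlation). The macrophage-like class was cluster 28, with neutrophil as its next best class (log2 score 1.85, against 2.63 for macrophage), and no cluster was named neutrophil. Neutrophils within the class were not told apart from a change in macrophages. Cox6a2, a respiratory chain subunit (1.48), and Hbb-bs, a haemoglobin chain (2.01), had the next smallest p-values and did not pass. Cd74 (0.16), H2-Aa (0.10), H2-Ab1 (0.02), H2-Eb1 (0.20), Ciita (0.12) and Nf1 (-0.24) did not pass. edgeR called 0 of 11299 genes with 263 at an unadjusted p under 0.05 (609 without Nf1+/- allograft 1 and 95 without wild-type allograft 2), and DESeq2 called 2, S100a8 and S100a9.

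In microglia-like nuclei, Plxna2, a semaphorin receptor (log2 -1.64), Thsd7a, a matrix-binding protein (-1.26), and Aff3, a transcription elongation factor (-1.46), had the smallest p-values and did not pass. Cd74 stood at 164 ± 107 CPM (n = 3) and 425 ± 381 CPM (n = 3), a log2 difference of -1.38 (SE 0.88) that did not pass, nor did H2-Aa (-1.45), H2-Ab1 (-1.63), H2-Eb1 (-1.44) or Nf1 (0.05). Most microglia-like nuclei of Nf1+/- allograft 1 were in cluster 1 with those of the shams, and those of the other 5 allografts were mostly in cluster 21. edgeR called 0 of 11634 genes with 409 at an unadjusted p under 0.05 (1183 and 703 without Nf1+/- allografts 1 and 3, 162 and 216 without wild-type allografts 2 and 3), and DESeq2 called 2, the haemoglobin genes Hba-a1 and Hba-a2. With camera, proliferation (0 of 25 positive, 1.4e-11) and RAS/MAPK output genes (0 of 14 positive, 6.8e-06) were lower, and homeostatic microglia genes (14 of 14 positive, 2.9e-06) were higher. With an estimated correlation each of these had an adjusted p of 0.757, 0 genes of any of them passed when adjusted over the list alone, and the lowest of their fry values was 0.361.

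The remaining classes gave 0 calls in edgeR and 0 in DESeq2 each. At an unadjusted p under 0.05 there were 260 genes in astrocyte-like, 151 in neuron-like, 176 in OPC-like and 109 in T/NK-like nuclei and 150 in the sum of all nuclei. Without Nf1+/- allografts 1, 2 and 3 in turn these were 998, 583 and 547 in astrocyte-like, 1388, 202 and 178 in neuron-like, 866, 397 and 335 in OPC-like and 382, 237 and 163 in T/NK-like nuclei and 302, 933 and 181 in all nuclei. Without wild-type allografts 1, 2 and 3 in turn they were 282, 125 and 114, then 227, 110 and 48, then 158, 86 and 89, then 136, 35 and 82, and then 176, 115 and 115 in the same order of classes. The smallest p-values belonged to Hcfc1r1 (1.96), Ncapd2 (-1.56) and the kinesin Cenpe (-1.66) in astrocyte-like nuclei, Ucn (3.38), Gm48094 (0.95) and Blnk (-1.49) in neuron-like nuclei, and Hbb-bs (1.93), Prorsd1 (1.66) and Enho (1.62) in OPC-like nuclei. In T/NK-like nuclei they belonged to Ly6c2, a surface protein of effector T cells (2.37), Ptgds (3.42) and the integrin Itgae of resident T cells (-1.83), and in all nuclei to Aldh1a7 (2.12), Ido1 (-1.89) and Slc38a5 (-1.90). None passed. Cd74 differed by -1.54 in astrocyte-like, -1.75 in neuron-like, -2.19 in OPC-like and -1.28 in T/NK-like nuclei and -1.05 in all nuclei, without passing. Nf1 differed by -0.24 in astrocyte-like, 0.04 in neuron-like, -1.3e-04 in OPC-like and -0.45 in T/NK-like nuclei and -0.20 in all nuclei on the log2 scale, without passing. Leaving out Nf1+/- allograft 2 gave 2 calls in T/NK-like nuclei, the myelin gene Mal and Ptgds. Type I interferon genes in astrocyte-like nuclei (17 of 17 positive, camera adjusted p = 0.0193) were lost with an estimated correlation (0.736); mitochondrial RNA in that class (8 of 8 positive) had a camera adjusted p of 0.0193, 0.736 with an estimated correlation, and a fry adjusted p of 0.0301.

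The last comparison asked how host cells differ between allograft and sham brain. In microglia-like nuclei, 8 of 14 homeostatic genes fell, with a camera call on the list that was lost with an estimated correlation (0.456) and a fry adjusted p of 0.0140. The purinergic receptor P2ry12 fell by 2.49 (log2, SE 0.38; 250 ± 139 CPM in 6 allografts against 1794 and 1007 CPM in the Nf1+/- and wild-type sham), the selectin ligand Selplg by 3.34 (161 ± 116 against 1688 and 1320 CPM), the fructose transporter Slc2a5 by 3.75 and P2ry13 by 2.73. Of the proliferation genes 9 of 25 were called higher, with a camera call lost with an estimated correlation (0.559). Top2a, the mitotic topoisomerase, stood at 185 ± 61.1 CPM (n = 6) with 0 UMIs in both shams, at least 22.6-fold higher by a floor of 3 counts over the shams, Mki67 was at least 10.5-fold, Cenpf at least 9.37-fold and Kif11 at least 7.49-fold higher. The receptor kinase Axl rose by 3.17 and the chemokine Ccl4 was at least 12.5-fold higher, while the lipid receptor Trem2 fell by 1.73. The integrin Itgax had 3 sham counts (ratio 11.1, 95% counting interval 3.77 to 53.7).

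Glioma markers moved with the cell cycle genes in these sums: Met, the hepatocyte growth factor receptor and a marker of the glioma class, was at least 134-fold higher, and cluster 21 had glioma as its next best class (log2 score 1.26, against 2.61 for microglia). With free RNA subtracted, 18 of the 179 genes called higher were still called, and Top2a was not (adjusted p = 0.236). Other large rises were Zfpm2, a transcription cofactor (at least 31.0998-fold), and Lockd, a non-coding transcript (at least 10.75-fold). The vessel factor Angpt2 had 1 sham count (ratio 16.4, interval 2.92 to 648). The hormone transcripts Oxt and Avp (log2 -6.59), the sulfotransferase Sult1a1 (-4.81), the lipogenic factor Thrsp (-4.35) and the cadherin Cdh9 (-4.10) were among the largest falls; Oxt had 2 allograft counts (ratio 0.00157, interval 1.8e-04 to 0.00600). The stress gene Fkbp5 (-3.40), Il7r (-3.50), the scavenger receptor Stab1 (-2.09), Sparc (-2.02), Vsir (-1.76) and Tgfb1 (-1.20) fell. Cd74 did not pass (log2 -2.48, SE 1.64), with 2888 CPM in the Nf1+/- sham, whose sum held 12 nuclei, and 20.6 CPM in the wild-type sham. H2-Aa (-2.02), H2-Ab1 (-1.25), H2-Eb1 (-2.56) and Nf1 (0.49) did not pass.

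edgeR called 349 of 12640 genes in microglia-like nuclei, 179 higher and 170 lower (51.3% higher), and DESeq2 called 1024 (61.7% higher). Without the Nf1+/- sham or without the wild-type sham the count was 0. It was 3081 without Nf1+/- allograft 1, 104 and 131 without Nf1+/- allografts 2 and 3, and 73, 49 and 33 without wild-type allografts 1, 2 and 3. P2ry12 kept its direction but missed the threshold without wild-type allograft 1 (adjusted p = 0.0510), 2 (0.0603) or 3 (0.0584), without the Nf1+/- sham (0.125) and without the wild-type sham (0.383). Top2a did so without the Nf1+/- sham (0.0595) and without the wild-type sham (0.285). Sham microglia-like nuclei lay mostly in cluster 1, as did 1274 of the 1300 of Nf1+/- allograft 1, and those of the other allografts lay mostly in clusters 21 and 35. Met ran at 161 CPM in Nf1+/- allograft 1 and between 1044 and 1579 CPM in the others. P2ry12 stood at 526 CPM in Nf1+/- allograft 1 and at 146 to 239 CPM in the others. Selplg stood at 396 against 100 to 143 CPM, and both genes were below both shams in every allograft. Trem2 did not follow this order (256 against 178 to 413 CPM). Glioma RNA in a sum lowers the CPM of host genes, and how much of these falls it made was not measured.

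Of the homeostatic microglia list, 8 of 14 genes fell (12 passed when adjusted over the list alone; camera adjusted p = 6.5e-17, 0.456 with an estimated correlation, fry 0.0140). Of the proliferation list, 9 of 25 rose (23 when adjusted over the list alone; camera 1.7e-09, 0.559 with an estimated correlation, fry 0.0858). Of the disease-associated microglia list, 3 rose and 1 fell of 20 (11 when adjusted over the list alone; camera 0.00105, 0.577 with an estimated correlation). Of the glioma markers, 4 of 18 rose (13 when adjusted over the list alone; camera 1.7e-05, 0.188 with an estimated correlation). Of the neuron markers, 2 of 15 fell (11 when adjusted over the list alone; camera 5.4e-07, 0.0539 with an estimated correlation, fry 0.00518), and of the microglia markers 5 of 11 (10 when adjusted over the list alone; camera 1.0e-13, 0.0539 with an estimated correlation, fry 0.00250).

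**Figure D4:**
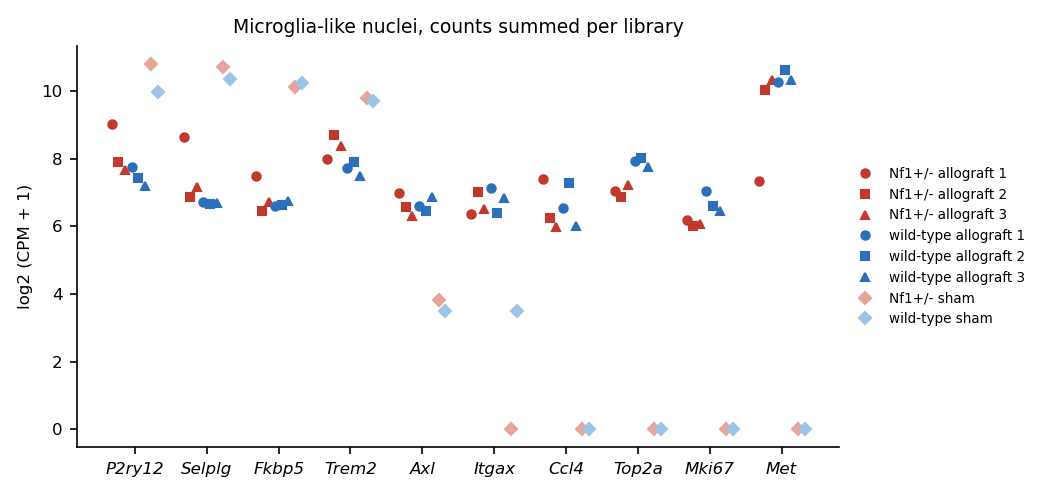
log2 (CPM + 1) (y axis) of 10 named genes (x axis) in microglia-like nuclei for the 6 allograft libraries and the 2 shams (points). P2ry12 and Selplg lie lower in all 6 allografts than in both shams, and Top2a has 0 UMIs in the shams.

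In oligodendrocyte-like nuclei, 18 genes were called higher, interferon and MHC class I genes among them. At Leiden resolution 2 only 1 of the 18, Met, was still called, with free RNA subtracted 8 were, and with a 5% mitochondrial limit, where 2 libraries dropped out, 0 were. B2m, the light chain of class I molecules, rose by 5.80 (log2, SE 0.91; 597 ± 416 CPM in 6 allografts against 19.8 and 9.86 CPM in the Nf1+/- and wild-type sham), the class I chains H2-D1 by 4.21 and H2-K1 by 3.98, and the interferon-induced Ifi27l2a by 9.49 (1701 ± 1426 CPM, n = 6). The antiviral gene Rsad2 had 0 sham UMIs and was at least 22.3-fold higher. Ratios of summed counts were 132 (interval 36.6 to 1094, 2 sham counts) for Oasl2, 96.5 (17.3 to 3819, 1 count) for Irf7 and 88.7 (15.9 to 3511, 1 count) for the guanylate-binding Gbp7, interferon genes all, 45.1 (12.4 to 374, 2 counts) for the filament gene Vim and 45.6 (8.12 to 1807, 1 count) for AI506816. Most of the nuclei summed came from Nf1+/- allograft 1, where Vim stood at 23.6 CPM against 240 to 520 in the other 5 allografts, AI506816 at 16.3 against 93.9 to 176 and Oasl2 at 169 against 22.6 to 238. Without that library the ratios were 256 for Vim, 201 for AI506816, 95.02 for Oasl2, 165 for Irf7 and 147 for Gbp7. Met, with 0 sham UMIs, was at least 239.6-fold higher. Cd74 did not pass (3 sham counts, ratio 9.94, interval 3.35 to 48.6, and 29.3 without Nf1+/- allograft 1), nor did Nf1 (-0.49).

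Among the largest falls in oligodendrocyte-like nuclei were Avp (-7.26), Rasd2 (-5.82), the opioid precursor Penk (-4.76; 7.98 ± 4.58 CPM, n = 6, against 218 and 217 CPM) and Tac1 (-4.26). Oxt, at 0 in every allograft, was at least 542.5-fold lower by a floor of 3 counts over the allografts, or at least 59.3989-fold without Nf1+/- allograft 1, and Fkbp5 fell by 3.43. Of the neuron markers 1 of 10 fell (6 when adjusted over the list alone; camera 7.7e-05, 0.359 with an estimated correlation, fry 0.0259). edgeR called 46 of 5917 genes, 18 higher and 28 lower (39.1% higher), and DESeq2 585 (72.8% higher). The count was 0 without either the Nf1+/- or the wild-type sham, 2712 without Nf1+/- allograft 1, 24 without Nf1+/- allograft 2, and 25, 7 and 19 without wild-type allografts 1, 2 and 3. B2m missed the threshold at Leiden resolution 2 (adjusted p = 0.0624), with a 5% mitochondrial limit (0.462), and without wild-type allograft 2 (0.0608), the Nf1+/- sham (0.115) or the wild-type sham (0.641). The MHC class I list had 3 of 9 genes risen (8 when adjusted over the list alone; camera 3.8e-06, 0.313 with an estimated correlation, fry 0.0376) and the type I interferon list 5 of 13 (12 when adjusted over the list alone; camera 3.8e-06, 0.313, fry 0.0510). Sham nuclei lay mostly in cluster 20, those of Nf1+/- allograft 1 in cluster 7 and those of the other allografts, 21 to 75 nuclei each, in cluster 10. Cluster 36, unnamed though oligodendrocyte was its best class, held 169 to 928 nuclei in each of these other allografts and took no part. The allograft side thus rests on a part of such nuclei that the naming rule chose.

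In astrocyte-like nuclei, Met, a marker of the glioma class, was at least 344-fold higher (1146 ± 510 CPM, n = 6, 0 sham UMIs) and the mitotic kinesin Cenpe had a ratio of 21.3 (interval 3.77 to 848, 1 sham count), summed over 1615 nuclei of Nf1+/- allograft 1 (Cenpe at 11.4 CPM) and 77 to 214 of each other allograft (17.1 to 59.3 CPM). Without that library the Cenpe ratio was 40.6. The guidance factor Slit2 (-4.85), the striatal signalling protein Ppp1r1b (-4.35), Penk (-3.56) and the sulfotransferase Chst1 (-2.74) fell, as did Oxt (3 allograft counts, ratio 0.00418, interval 8.5e-04 to 0.0126, and 0.00782 without Nf1+/- allograft 1). With free RNA subtracted, 0 of the 2 genes called higher and 0 of the 12 called lower were still called. Cd74 (3.51, SE 1.25), H2-Ab1 and H2-Eb1 (0 sham UMIs each), H2-Aa (1 sham count) and Nf1 (0.05) did not pass. edgeR called 14 of 10424 genes, 2 higher and 12 lower (14.3% higher), and DESeq2 895 (72.0% higher). The count was 0 without the Nf1+/- sham, the wild-type sham or wild-type allograft 1, 3254 without Nf1+/- allograft 1, 7 and 6 without Nf1+/- allografts 2 and 3, and 6 and 4 without wild-type allografts 2 and 3. Sham nuclei and nearly all of Nf1+/- allograft 1 lay in cluster 5, and those of the other allografts in cluster 34.

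In neuron-like nuclei, the chemokine Ccl4 rose by 4.47 (2.47 ± 0.612 CPM, n = 6, against 0.131 and 0.0854 CPM). Mbp fell by 1.96 (61.5 ± 12.2 CPM, n = 6, against 261 and 218 CPM), Prr5l, a regulator of mTORC2, by 2.21, the vesicular GABA transporter Slc32a1 by 1.68, the potassium channel Kcnk13 by 1.40, Aplp1 by 1.29 and Car11 by 1.25. Mbp is a marker of the oligodendrocyte class, and Prr5l was among the 10 top genes of cluster 7, named oligodendrocyte. Whether the falls of Mbp and Prr5l arose in neurons was not tested. Cd74 (4.54, SE 1.48), H2-Aa (6.21), H2-Ab1 (5.26), H2-Eb1 (5.14), Ciita (1.15) and Nf1 (-0.39) did not pass. edgeR called 14 of 20012 genes, 3 higher and 11 lower (21.4% higher), and DESeq2 2744 (65.1% higher). With free RNA subtracted, 0 of the 3 genes called higher and 1 of the 11 called lower were still called. With doublets kept and with a naming gap of 0.4, 0 of the 3 and 0 of the 11 were. With the replicate number as a block many more genes passed, these 14 among them. The count of edgeR calls was 5490 without Nf1+/- allograft 1. It was 0 without any 1 of the Nf1+/- allografts 2 and 3, the wild-type allografts 1, 2 and 3 and both shams. Type I interferon genes had 0 of 20 called and 16 when adjusted over the list alone (camera 4.3e-08, 0.424 with an estimated correlation). Sham neuron-like nuclei lay mostly in clusters 19 and 24 and those of Nf1+/- allograft 1 in clusters 0 and 4, and those of the other allografts in several others, among them 26 and 31. Differences between classes in what was called were not tested.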

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

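The tests of technical explanations named here were of mixed origin: those of myeloid doublets and of free RNA from glioma cells were chosen before the results, and the tests of free RNA from myeloid cells and from sham neurons only after the result was seen. Multiplexing oligos, which no comparison used, gave a signal in the in vitro matrices. In matrix 1, 85.7% of oligo UMIs came from CMO305, and in matrix 2, 84.4% came from CMO306. No sample without these oligos was there to compare with. A test for a sample far from its group was not made, since each genotype had 3 allografts and 1 sham.

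The first pattern weighed was Cd74 UMIs in glioma-like nuclei. If they were free RNA from myeloid cells, Cd74 and myeloid markers should lie in the same ratio in glioma-like nuclei and RP-rich droplets. The median log2 of that quotient over 5 libraries was -0.197, within the range set for this explanation. Free RNA may thus account for much of the Cd74 signal. RP-rich droplets carry glioma markers, so they are not a pure measure of free RNA. Cd74 over myeloid marker CPM in glioma-like nuclei was 0.0330, 0.133 and 0.0738 in Nf1+/- allografts 1 to 3. In wild-type allografts 1 to 3 it was 0.0282, 0.299 and 0.345. Neuron-like nuclei of the same libraries had 0.0240, 0.129, 0.0752, 0.0368, 0.297 and 0.338. A biological source, Cd74 made by some glioma cells, was not ruled out by these values.

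The next pattern was the set of Cd74-positive nuclei. Microglia and macrophage markers had a median log2 fold change of 0.0614 in them (16 genes), against 0.246 for the other MHC class II genes (6 genes) and 0.433 for Y genes (3 genes), which mark male host nuclei. With nuclei thinned to 1000 UMIs, the macrophage gene Lyz2 was called higher (log2 1.29). Doublets or fragments of myeloid nuclei could therefore not be told from glioma cells that make class II genes, since neither prediction was met.

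The last pattern was the difference of microglia-like nuclei between allograft and sham, with glioma-only genes at 0.581 to 0.680 of their RP-rich level in 5 allografts (medians), at 0.594 to 0.826 in T/NK-like and at 0.187 to 0.338 in neuron-like nuclei. With the RP-rich profile subtracted (not in Nf1+/- allograft 1, whose 59 RP-rich droplets gave no estimate), 10.1% of the genes called higher (18 of 179) were still called higher, and in neuron-like nuclei 0 of 3 were (0%). Both values lay within the range set beforehand for this explanation, so free RNA from glioma cells may explain many of the rises. Of the microglia-like falls, 15.9% (27 of 170) were still called. The subtraction took out the RP-rich profile at the medians given above. That raises the share of the host genes left, so falls can shrink with it as well as rises. The test therefore cannot tell free RNA from lost power. Of the falls, 10.6% were genes at a higher level in sham neurons, against 39.5% of genes not called, so free RNA from sham neurons is an unlikely source of most of them. P2ry12 passed as lower in the fit with the subtraction (log2 -1.76, edgeR adjusted p = 0.0167), so a change of the microglia themselves was not excluded.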

How the results depend on the processing

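The tests with a 5% mitochondrial limit, RP-rich droplets kept, a naming gap of 0.4, free RNA subtracted, expected Cd74 shares and the replicate block in the sham comparisons were chosen only after the result was seen. Over all alternatives, 67 of the values of shares kept direction and side of the threshold and 2 reversed, 146 counts of calls stayed within 1.5 times and 72 moved. Of values of named genes past the threshold, 789 stayed past it, 453 kept their direction but missed it and 2 reversed; of those not past it, 1306 stayed so, 26 passed and 49 reversed. The cause was not tested unless stated. The sham comparisons held few nuclei in places, 12 in the microglia-like sum of the Nf1+/- sham. Leaving out single allografts moved their counts too, and what limits the calls was not tested.

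DESeq2 called 1024 genes between allograft and sham in microglia-like, 895 in astrocyte-like, 585 in oligodendrocyte-like and 2744 in neuron-like nuclei, 1 between Cd74-positive and Cd74-negative nuclei, and between genotypes 1 in glioma-like, 2 in microglia-like and 2 in macrophage-like nuclei. Without a filter on low counts the sham counts were 939, 1042, 685 and 38 in the same order of classes, the Cd74 count 16, and the genotype counts 24 in macrophage-like, 20 in T/NK-like and 1 in OPC-like nuclei (Cartpt). Leiden resolution 2 gave 9 in astrocyte-like and 29 in oligodendrocyte-like nuclei and 11 for Cd74. With doublets kept the counts were 26 in astrocyte-like and 0 in neuron-like nuclei and 3 for Cd74 (Ptprc, Rbm47 and Ttr, chosen after their values were seen). With a 5% mitochondrial limit all 4 sham comparisons gave 0. The limit also took the Nf1+/- sham, left with 1 microglia-like, 1 astrocyte-like and 3 oligodendrocyte-like nuclei, out of those 3 comparisons and wild-type allograft 2 (6 nuclei) out of the oligodendrocyte-like one, and leaving out that sham alone gave 0 as well, so these moves cannot be put down to the limit itself. With the same limit Cd74 gave 3 (Cxcl10, Gm29904 and Ttr, chosen after their values were seen). With free RNA subtracted the sham counts were 76 in microglia-like, 0 in astrocyte-like, 16 in oligodendrocyte-like and 2 in neuron-like nuclei (Camk2n1 and Oxt, chosen after their values were seen). A naming gap of 0.4 gave 0 in neuron-like nuclei, and no genotype term gave 48 in astrocyte-like and 90 in neuron-like nuclei. Thinning to 1000 UMIs and leaving out nuclei with a myeloid marker UMI gave 3 each for Cd74.

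Leave-one-out counts ran from 0 to 3081 in microglia-like, 0 to 3254 in astrocyte-like, 0 to 2712 in oligodendrocyte-like and 0 to 5490 in neuron-like nuclei for allograft against sham, from 4 to 13 for Cd74 and from 0 to 2 for genotype in T/NK-like nuclei. Where a sham was left out, the lone sham was assumed to vary like the allografts. The T/NK-like share difference ran from -0.738 to 0.124 points, and the microglia-like difference as a share of host nuclei was -0.350.

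Values of Nf1 that reversed, all near 0, were 0.0115 (DESeq2 size factors) and 2.3e-04 (at least 1000 UMIs) for genotype in OPC-like nuclei. For Cd74-positive nuclei Nf1 had 0.00777 (Leiden resolution 2), 0.00148 (RP-rich droplets kept), 0.00442 (at least 2 Cd74 UMIs), 1.0e-05 (5% mitochondrial limit), 0.0482 (no myeloid marker UMI) and 0.136 (thinned to 1000 UMIs). Mbp had -0.0548 without nuclei with a myeloid marker UMI, and St18 -0.0589 when thinned to 1000 UMIs. With free RNA subtracted, genotype values were -0.112 for Ciita and -0.122 for H2-Ab1 in macrophage-like nuclei, and for Nf1 -0.113 in microglia-like and -0.0325 in neuron-like nuclei. H2-Ab1 in macrophage-like nuclei had -0.0448 without a filter on low counts and -0.0129 with a 5% mitochondrial limit. With that limit and without the Nf1+/- sham, which then held too few nuclei, allograft against sham in microglia-like nuclei gave 5.16 for Cd74, 10.71 for H2-Aa, 10.91 for H2-Ab1, 10.27 for H2-Eb1 and -0.0323 for Nf1, and Nf1 in astrocyte-like nuclei, also without that sham, -0.00292.

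Leave-one-out ranges of genes that reversed were, for genotype in macrophage-like nuclei, -0.144 to 0.366 (Cd74), -0.237 to 0.358 (H2-Aa), -0.298 to 0.242 (H2-Ab1), -0.123 to 0.420 (H2-Eb1) and -0.0605 to 0.339 (Ciita). Ciita ran from -0.494 to 0.275 in all nuclei and from -1.18 to 1.38 in neuron-like nuclei. Nf1 ran from -0.240 to 0.150 in neuron-like, -0.262 to 0.142 in OPC-like and -0.174 to 0.185 in microglia-like nuclei, from -0.108 to 0.258 for allograft against sham in astrocyte-like nuclei and from -0.0201 to 0.00567 for Cd74-positive nuclei. Allograft against sham in microglia-like nuclei ran from -4.07 to 4.44 (Cd74), -3.74 to 5.72 (H2-Aa), -3.00 to 3.67 (H2-Ab1) and -4.29 to 5.31 (H2-Eb1).

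With the replicate number as a block, the genotype tests called 0 genes in every class, and exact sign-flip tests of the shares gave p of 0.75 for glioma-like (difference -12.5), 0.25 for microglia-like (1.69), 0.25 for macrophage-like (-2.05), 1 for T/NK-like nuclei (-0.356) and 0.25 for Cd74 (-4.29), with 0.25 the smallest possible at n = 3 pairs. The block changed no call between genotypes. Correlations of same-numbered replicates 1, 2 and 3 were 0.541, -0.191 and 0.318 in glioma-like, 0.253, -0.0379 and 0.244 in microglia-like, 0.0321, -0.0224 and 0.0158 in macrophage-like, 0.125, 0.0515 and 0.178 in astrocyte-like, 0.201, -0.0467 and 0.231 in OPC-like, 0.122, 0.0459 and 0.235 in T/NK-like and 0.338, -0.294 and 0.417 in all nuclei. Not every sample correlated best with its own number. Allografts and shams share only number 1, so with the replicate block their difference came from 4 libraries, and the counts were 34 in microglia-like, 10 in astrocyte-like, 42 in oligodendrocyte-like and 1970 in neuron-like nuclei, with Nf1 at 0.0455 in oligodendrocyte-like nuclei.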

Other observations

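The in vitro sample was compared with glioma-like nuclei in vivo without a test, and since it is labelled polyA RNA and the brain libraries nuclear RNA, method and condition could not be told apart. Cd74 stood at 0.225 CPM in vitro (13 UMIs) and 23.3 ± 25.02 CPM (n = 6) in vivo. Free RNA from host cells, for which a culture has no source, was not separated from this difference. In the same 6 libraries Cd74 ran from 2.59 to 76.4 CPM in neuron-like and from 2.89 to 66.9 CPM in glioma-like nuclei. The difference can therefore not be assigned to the glioma cells, and the same limit holds for the gene lists below. In vitro and without thinning, a Cd74 UMI was seen in 2 of 536 cells (0.373%, exact 95% interval 0.0452% to 1.34%) and 10 of 1583 cells (0.632%, 0.303% to 1.16%). Median depths of these cells were 26269.5 and 24853 UMIs in matrices 1 and 2. The shares can therefore not be set beside the thinned shares of glioma-like nuclei. Median log2 ratios of in vivo over in vitro, with the percentile among 10000 random lists of like expression, were 1.58 (99.9) for MHC class II, 0.60 (85.2) for MHC class I, 0.83 (99.7) for interferon gamma response and 1.06 (99.98) for type I interferon response. They were 0.23 (31.2) for co-stimulation and checkpoint ligands, -0.67 (1.09) for RAS/MAPK output, -0.52 (1.69) for proliferation, 0.23 (27.3) for mesenchymal glioma, -0.92 (0) for hypoxia and angiogenesis and 1.07 (97.5) for extracellular matrix. Homeostatic microglia genes had 1.08 (99.2), disease-associated microglia genes 0.49 (85.7), chemokines and cytokines 0.69 (86.8), tumour-associated macrophage suppression 0.37 (42.9), reactive astrocyte 0.67 (88.8) and oligodendrocyte stress 0.72 (88.2). T cell state had 0.13 (22.6), immediate early and dissociation stress -1.79 (0), mitochondrial RNA 0.35 (93.3) and sex-linked genes 0.62 (99.99).

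The tests by regrouping libraries were chosen only after the result was seen. In glioma-like nuclei the genotypes gave 0 calls, and the grouping of Nf1+/- allograft 1 with wild-type allografts 1 and 2 gave 3888, which points to a structure of the samples other than genotype. Between the 3 libraries above 0 and the 3 below 0 on the first component, 84 of 93 ribosomal protein genes (median log2 1.02), 8 of 8 mitochondrial transcripts (0.48), 6 of 7 MHC class II genes (1.23) and 17 of 19 mesenchymal glioma genes (0.90) were higher above 0. Of 9 oligodendrocyte markers 1 (-0.77) and of 16 neuron markers 3 (-0.53) were higher. These lists were looked at after the grouping was seen.

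For every genotype comparison the real count was 0, which any grouping reaches, so 10 of 10 groupings did by construction and the comparison says nothing on chance. The groupings are also too few for a share under 0.05. The highest count of another grouping was 3888 in glioma-like, 2 in macrophage-like and 1 in T/NK-like nuclei and 0 in microglia-like, astrocyte-like, neuron-like and OPC-like nuclei and in all nuclei. For Cd74-positive against Cd74-negative sums, 4 of 32 assignments within libraries, the real one included, called at least the 6 genes of the real one, and the highest other called 8. By this count chance was not excluded, but it is a weak test, since the 3 others exchanged only 1 or 2 of the 6 libraries and kept much of the real contrast. The 10 assignments that exchanged 3 libraries called 0 to 4 genes.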
